A study of Mus musculus with 23 samples.

How the data were processed

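RNA was measured in 6 libraries from C3H10T1/2 cells, a mouse mesenchymal stem cell line that can be turned into fat cells. Per the labels' protocols, cells were grown with BMP7 and then differentiated with dexamethasone, IBMX, insulin, a compound labelled Rosi and T3. Day 0 stands for pre-adipocytes and day 7 for mature adipocytes. At each day 1 library was made by a standard procedure and 1 by TELP, the library construction method that the series is about, under the label N9. Day 7 has a further TELP library labelled N9_ss and another labelled T18, and the labels do not spell out N9, ss or T18. The series lists 23 samples. The other 17 are chromatin immunoprecipitation libraries, which were not analysed here.

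The authors deposited RPKM values, reads scaled to the length of the gene model and to the read total, for 24029 genes with 1 column per RNA library. Bowtie2, TopHat and Cufflinks are named per the submitters' processing notes, with the mm9 build. Their versions, settings, annotation and strand handling are not given in the sources used here, nor is the read total behind the RPKM. Genes were named as in the deposited table, and 22857 of its symbols (95.1%) matched a list of current mouse gene names. No coordinates are given, because the annotation at hand is of another build than mm9.

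Sequencing depth was estimated from the low values, which step in whole multiples of what 1 read is worth. Ratios of these steps gave the relative depth of libraries. Going round the standard and TELP N9 libraries of both days returned a product of 1.0002. In that round the ratio of standard to TELP N9 at day 0 rested on 72 of 3225 low genes. The depths of N9_ss and T18 each rest on 1 ratio outside it and were not checked this way. Genes with a short annotated length, not filtered for introns, gave the absolute scale. Among 321 such genes, 57 lay at a common depth once 202 bp had been deducted from each length. That scale therefore rests on a minority of these genes and is approximate. Whole reads could be recovered for 2987 genes, so no count test was run. These were 20.3% of the genes searched, which had no upper limit of expression, although the search stopped at 250 reads.

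All comparisons used log2(RPKM + 1). Such folds understate the change of genes with low values. Genes with a mean of at least 1 RPKM over the libraries compared were kept, and a gene was called higher or lower at an absolute log2 difference of at least 1. Every group holds 1 library, so no difference has a replicate check and no p-value is given outside the limma fit described below. A call in both library types is a technical agreement only, since nothing says that the RNA came from separate cultures. An exact 0 can be a failed estimate, because genes that all cells use were also at 0 in some libraries, so such genes are described as listed at 0.

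24 gene lists were fixed before the data were examined. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The resulting percentile describes these libraries and is not a p-value. Intervals of medians come from 2000 resamplings of the members, and cover the spread of members only. Lists with fewer than 3 measured members received no median. The mitochondrially encoded list had 0 members in the table.

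Named genes followed a rule set in advance. For day 7 against day 0 it took Pparg, Cebpa, Fabp4, Adipoq, Ucp1 and Dlk1, up to 2 members of each list called in both library types, and the 5 highest and 5 lowest genes. For TELP N9 against standard it took the 6 highest and 6 lowest at both days. For the N9_ss and T18 libraries it took the 6 highest, the 6 lowest and up to 3 called members of lists outside the central 95% of random lists. The 5 genes with the largest difference of folds completed it. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

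Alternatives planned in advance were a pseudocount of 0.1 RPKM, no filter, a filter at 5 RPKM, 3 other scalings, the N9_ss or T18 library in place of N9, and limma with library type as a block. The scalings were median of ratios, equal totals and quantile normalization. The limma fit used 4 libraries and has 1 residual degree of freedom, and its spread is that between library types, not between cultures. Counts without small noncoding RNAs and without genes listed at 0 were added after seeing the data. Calls by size were tested on simulated data for day 7 against day 0 over 11299 genes. They found 86% of genes raised and 68% of genes lowered by 1.5 log2 units, 100% of those changed by 3 units, and 0% of unchanged genes. The simulation held read sampling at one gene length and small random noise, with no effect of library type, and changed only genes at 5 RPKM or more. In the data the folds of the library types differed with an SD of 1.30, or 0.89 without small noncoding RNAs, so these rates do not carry over. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.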

Results

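Gene expression was compared between pre-adipocytes (day 0) and mature adipocytes (day 7) of the C3H10T1/2 line, in libraries made by a standard procedure and by TELP. The table holds 6 labelled libraries, 1 per group, so no value below has a replicate error. Estimated depth was 14400000 fragments for standard day 0, 14200000 for standard day 7 and 22600000 for TELP N9 day 0. The day 7 TELP libraries were shallower, at 5500000 for N9, 5760000 for N9_ss and 4760000 for T18. At 1 RPKM a transcript of 2 kb then rests on 25.9, 25.5, 40.7, 9.89, 10.4 and 8.56 reads in that order. Genes at 1 RPKM or more numbered 11129 and 11112 in the standard libraries and 11306, 10351, 10306 and 6797 in the TELP libraries. The 10 genes with most RPKM held 7.56% and 9.80% of the total in the standard libraries at day 0 and day 7. They held 15.2% in TELP N9 day 0, 32.8% in N9 day 7, 31.6% in N9_ss and 79.8% in T18.

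The first comparison asked how expression differed between adipocytes and pre-adipocytes. Genes of the fat cell were far higher at day 7 in both library types. Fabp4, a fatty acid carrier of adipocytes, was at 6.99 RPKM at day 0 and 10253 at day 7 in the standard libraries, and at 3.93 and 24892 in TELP N9. Adipoq, which encodes the hormone adiponectin, was higher by 9.64 and 10.30 log2 units in the standard and TELP N9 libraries. Cidec, a lipid droplet protein, was higher by 9.87 and 10.83 units, and Gpd1 by 9.90 and 10.38. Pparg and Cebpa, transcription factors that drive adipogenesis, were higher by 1.40 and 3.62 units in the standard libraries and by 2.24 and 5.02 in TELP N9, and with library type as block Cebpa passed limma at a false discovery rate of 0.05 (adjusted p 0.0384) and Pparg did not (0.0934). Of 27 measured adipocyte identity genes, 26 were higher in both library types and 0 were lower. Their median fold was 5.00 (4.28 to 7.08) in the standard and 6.69 (5.61 to 8.61) in the TELP N9 libraries, at percentile 100 of random lists in both.

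Most lipid synthesis and mitochondrial genes were called higher as well, but few of the mitochondrial calls passed limma with library type as block. Among 18 lipogenesis genes 15 were higher in both types, led by Acsl1 at 7.22 and 8.45 units and Agpat2 at 6.44 and 7.40. Elovl6, a fatty acid elongase chosen after its values were seen, was the 1 member lower in both, at -1.38 and -2.58. Of 22 fatty acid oxidation genes 20 were higher, including Acaa1b (4.87 and 7.33) and Ehhadh (5.70 and 6.03). The TCA cycle had 14 of 16 higher, with Idh3a at 2.93 and 4.25 units and Dlat at 2.47 and 3.51. Oxidative phosphorylation had 34 of 40 higher, with Cycs, the electron carrier cytochrome c, at 3.06 and 3.87 and Uqcrfs1 at 2.36 and 4.10. Medians of these lists in the standard and TELP N9 libraries were 2.90 and 3.75 for lipogenesis, 2.27 and 3.10 for fatty acid oxidation, 1.71 and 2.75 for the TCA cycle, and 1.38 and 2.11 for oxidative phosphorylation. All these medians lay at percentile 100. Calls that passed limma were 9 of 15 for lipogenesis, 5 of 20 for fatty acid oxidation, 2 of 14 for the TCA cycle and 1 of 34 for oxidative phosphorylation, and Dlat and Uqcrfs1 did not pass. Thermogenic genes had a median of 2.39 and 4.03, with 13 of 16 higher in both, 3 of them past limma. Cox8b was listed at 0 in both day 0 libraries and stood at 70.2 and 472 RPKM at day 7, and Cox7a1, which did not pass limma, reached 9.10 and 112 RPKM. Ucp1, the uncoupling protein of brown fat, was listed at 0 in both standard libraries and in TELP N9 day 0, and was at 0.882 RPKM in N9 day 7, under the filter.

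Some precursor genes and most contractile genes were called lower at day 7, though none of these calls passed limma with library type as block. Dlk1, a preadipocyte marker, went from 5.60 to 0.784 RPKM in the standard libraries and from 7.77 to 0.395 in TELP N9. Sox9 differed by -1.30 and -3.66 log2 units and Gata2 by -1.79 and -3.16, and 6 of 17 preadipocyte and anti-adipogenic genes were lower in both types. The contractile cytoskeleton had 11 of 16 genes lower and 0 higher, led by Myl9 (-2.57 and -5.15) and Tpm1 (-2.37 and -3.79). Its median was -1.38 and -2.07, against -0.95 and -2.45 for the preadipocyte list. Extracellular matrix genes went both ways, with 4 of 29 lower, among them Tnc (-3.20 and -4.30), and 3 higher, among them Col15a1 (3.37 and 4.38). Their median was -0.67 in the standard and -2.31 in the TELP N9 libraries. Medians of cytosolic ribosomal protein genes were -0.75 and -1.36, though Rps12 alone of 82 was called lower in both. These medians all lay at or below percentile 0.01.

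BMP and TGF-beta targets had medians of -0.51 and -1.35 (percentiles 1.45 and 0.84). Grem1 (-1.19 and -5.98) and Tgfbi (-2.70 and -4.18) were among 5 of 13 lower, and 1 was higher. Replication-dependent histone genes had medians of 0.92 and 1.41 at percentile 100, with 18 of 47 higher, 1 of them past limma, and 1 lower. Hist1h4h was higher by 3.66 and 5.25 units, and Hist1h4j, which did not pass, by 2.86 and 4.52, but near-identical copies can share reads, so single histone genes are uncertain. Interferon and inflammation genes had medians of -0.25 and -1.73, with 4 of 15 lower in both. Of these, Cxcl5 went from 29.8 to 4.85 RPKM in the standard libraries and Ccl2 from 10.2 to 3.98, and both were listed at 0 in N9 day 7. Glucocorticoid targets had medians of -0.22 and 0.32 (percentiles 37.5 and 97.1), with Zbtb16 higher (1.21 and 1.95) and Cebpd lower (-1.72 and -2.31). Stress and early response genes had medians of -0.25 and 0.22 (percentiles 31.3 and 95.9). Trib3 was higher (1.27 and 3.43) and Egr1 lower (-2.27 and -1.29). Nuclear long noncoding RNAs had medians of -0.54 and -1.13 over 5 members (percentiles 9.81 and 13.7). Of these, Meg3 (-1.35 and -3.95) and Airn (-1.32 and -3.89) were lower. Medians of the glucocorticoid, stress and nuclear long noncoding RNA lists lay inside the central 95% of random lists in both types.

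Markers of other cell types were few. Runx2, a regulator of bone formation, was lower by size (-1.20 and -2.49). The 4 measured osteoblast markers had medians of -0.50 and -1.61 (percentiles 10.8 and 3.18), both inside the central 95% of random lists. Col2a1 (-2.23 and -1.77) was the 1 of 2 measured chondrocyte markers called lower. Acta1 (-1.05 and -2.16), the 1 measured muscle marker, was lower. Tek, the 1 measured endothelial marker, went from 11.2 to 1.18 RPKM in the standard libraries and was listed at 0 in N9 day 7. Neither of the 2 measured macrophage and leukocyte markers was called in both types.

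**Figure D1:**
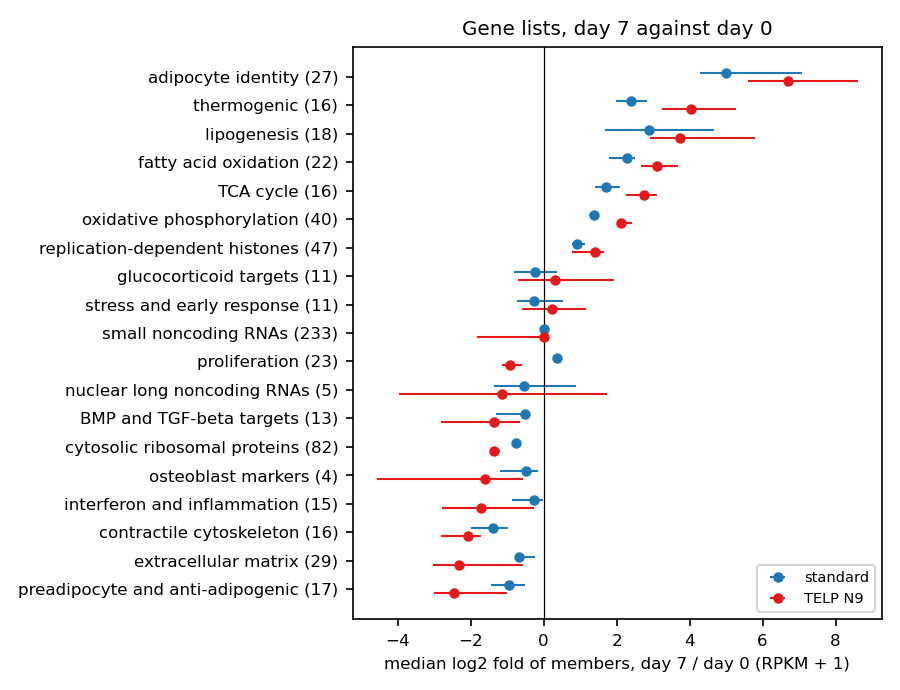
Median log2 fold of RPKM + 1 at day 7 over day 0 for each gene list, with the number of measured members in brackets, in standard (blue) and TELP N9 (red) libraries. Lines are 95% intervals from resampling members. The adipocyte identity list is highest, at 5.00 and 6.69, and proliferation lies on opposite sides of 0, at 0.36 and -0.92.

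Over all 11474 genes kept, 830 were higher and 667 lower at day 7 in both library types. Independent lists would share 128 and 221. The standard libraries alone gave 952 higher and 740 lower, and TELP N9 alone 1545 and 3424. By the rule, the 5 highest genes were Fabp4, Adipoq, Cidec, Gpd1 and Mir6986, and the 5 lowest were all small noncoding RNAs (Mir5113, Snord16a, Snord2, Snord12 and Mir374b). Chosen after their values were seen, with small noncoding RNAs and genes listed at 0 left out, the lowest included Tnc, Spon2 (-3.37 and -3.95), Plk2 (-2.93 and -4.15), Clec11a (-2.88 and -3.63) and Npy1r (-2.87 and -5.04). Folds of the library types had r = 0.642 and rho = 0.776 across genes, which are not independent replicates, and r = 0.844 without small noncoding RNAs. Limma with library type as block, at a false discovery rate of 0.05, called 162 higher and 24 lower, all within the calls by size, and 3137 genes had an unadjusted p under 0.05. Small noncoding RNAs made up 12 of the 24 lower and 5 of the 162 higher. The 23 adipocyte identity genes past this test compare with 0 preadipocyte genes and 0 contractile genes. Besides small noncoding RNAs, the matrix list was the only list with a lower gene past it, and had 1. Lists of signalling, inflammation, stress, nuclear long noncoding RNAs and other cell types had 0 genes past it. Scaling mattered for the balance. Of the genes called in both types 55.4% were higher, against 67.6% (994 higher, 476 lower) under median of ratios, and in TELP N9 alone 31.1%, 48.1% under median of ratios and 17.1% under equal totals. The median of all genes was -0.17 in the standard and -0.46 in the TELP N9 libraries, and under median of ratios -0.04 and -0.07.

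**Figure D2:**
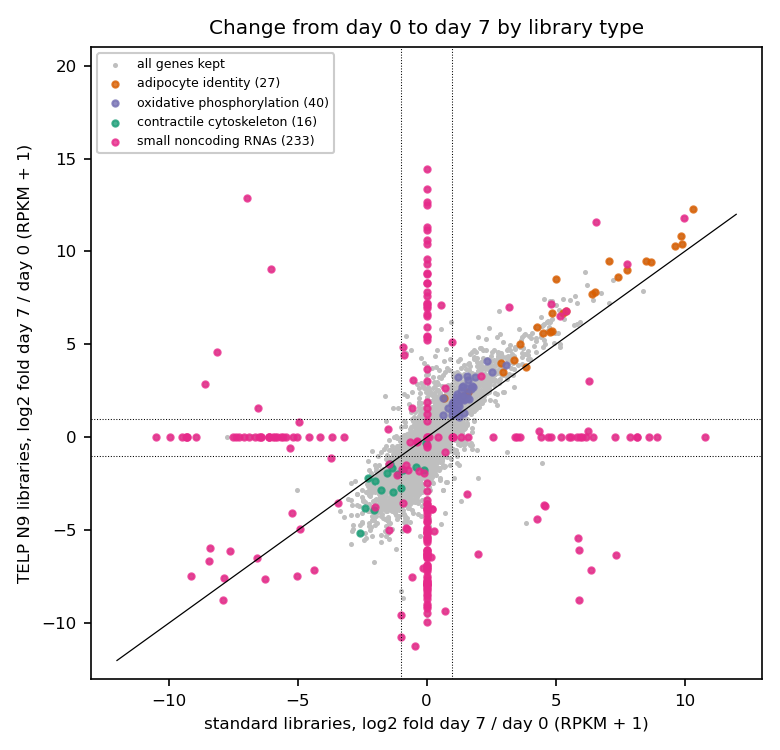
Log2 fold of RPKM + 1 at day 7 over day 0 for 11474 genes, standard libraries on the x axis and TELP N9 on the y axis. Colours mark 4 gene lists, the diagonal marks equal folds and dotted lines the threshold of 1. Adipocyte genes lie high on both axes (medians 5.00 and 6.69), and many small noncoding RNAs lie on an axis, listed at or near 0 in both libraries of the other type.

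The second comparison set TELP N9 against the standard procedure on each day. At day 0 the median differences (TELP N9 minus standard) of metabolic and adipocyte lists were small. They were 0.06 for adipocyte identity, 0.18 for oxidative phosphorylation and -0.14 (percentile 1.95) for the TCA cycle. Several adipocyte genes were under 1 RPKM at day 0 in both types, such as Adipoq (0.675 and 0.601) and Cidec (0.371 and 0.294). Log2(RPKM + 1) holds the difference of such genes small, so the day 0 adipocyte median says little about agreement of the types. At day 7 the adipocyte list was 1.21 higher in TELP N9, oxidative phosphorylation 0.99, fatty acid oxidation 0.96 and thermogenic genes 1.76. Extracellular matrix genes had a median of -0.26 (percentile 0) at day 0 and -2.09 at day 7, the contractile list -0.09 and -1.21, and proliferation 0.08 and -1.35. Fabp4 differed by -0.70 at day 0 and 1.28 at day 7, Cebpa by 0.35 and 1.76, and Grem1 by 0.39 and -4.40. Cytosolic ribosomal protein genes were 0.58 higher in TELP N9 at day 0 (percentile 100), with 20 of 82 called higher, and at -0.03 at day 7, where median of ratios gives 0.24. Replication-dependent histone genes had medians of 0.44 at day 0 and 0.96 at day 7, both at percentile 100. Of 47 measured, 7 were called higher and 1 lower at day 0, and 22 higher and 1 lower at day 7.

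Calls numbered 235 higher and 82 lower in TELP N9 at day 0, and 803 and 1917 at day 7. At day 0, 74.1% of calls were higher, and 61.6% under equal totals. At day 7 the share was 29.5%, 47.2% under median of ratios and 4.88% under equal totals. At both days 69 genes were higher in TELP N9 and 22 lower, where independent lists would share 16.4 and 13.7. Of the 69, 11 were small noncoding RNAs and 9 ribosomal protein genes, and 17 of the 22 were small noncoding RNAs. Snord65, Mir8114, Snord49a, Mir697, Mir148a and Snord83b led the higher group. Snord49a was listed at 0 in the standard libraries and at 134 and 86429.8 RPKM in TELP N9. Mir1892, Snord4a, Snord96a, Mir8094, Mir3060 and Snora28 led the lower group, with Snord4a at 467 and 1184 RPKM in the standard libraries and listed at 0 in TELP N9. Chosen after their values were seen, with small noncoding RNAs and genes listed at 0 left out, Romo1 (2.90 and 3.25), Oaz1 (2.44 and 2.56) and Rplp2 (2.17 and 1.99) were the highest at both days besides Rpl26 and Rps27. The pseudogene Oaz1-ps differed the other way, by -1.95 and -6.80, and the sum of both genes by 1.28 and 1.06, so the value of Oaz1 is uncertain. Rps27rt, a copy of Rps27, differed by 0.95 and -6.36. Rpl26 was at 0.00046 RPKM in standard day 0 and 32.5 in TELP N9 day 0, although ribosomes of all cells use it. Levels had r = 0.886 and rho = 0.924 across genes at day 0, and r = 0.790 and rho = 0.814 at day 7.

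**Figure D3:**
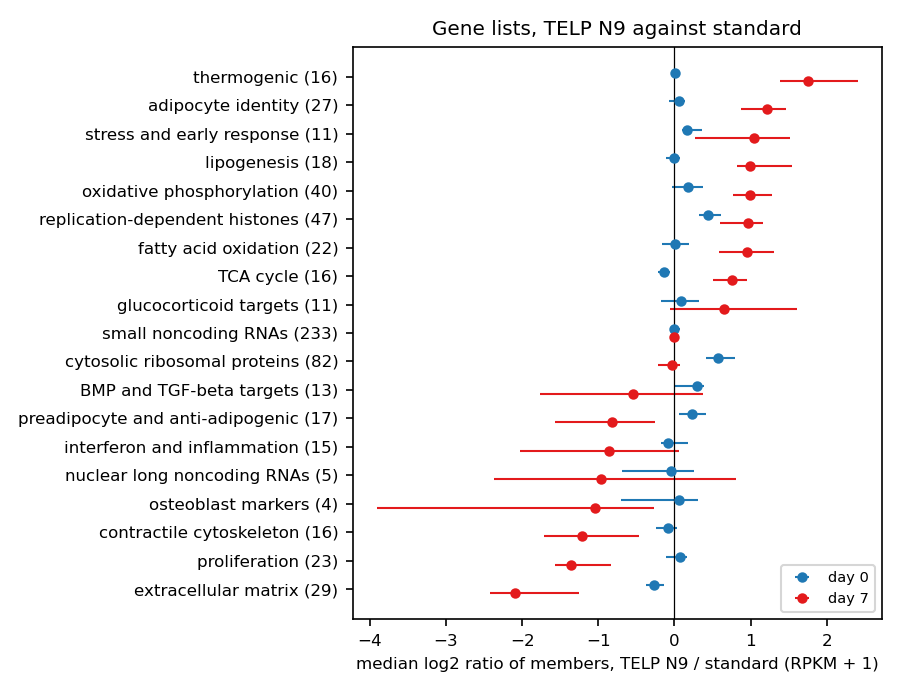
Median log2 ratio of RPKM + 1, TELP N9 over standard, for each gene list at day 0 (blue) and day 7 (red), with 95% intervals from resampling members. Thermogenic genes are highest at day 7 (1.76) and extracellular matrix genes lowest (-2.09), while the day 0 medians of these lists are 0.01 and -0.26. Some thermogenic genes had very low values at day 0, such as Cpt1b at 0.0172 (standard) and 0.0211 RPKM (TELP N9). Their day 0 difference is thereby held small.

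The third comparison asked whether the change from day 0 to day 7 differed with library type. Proliferation genes had a median fold of 0.36 (0.25 to 0.48) in the standard libraries and -0.92 (-1.14 to -0.60) in TELP N9. The standard value lay at percentile 100 of random lists, and the TELP N9 value at 5.05, inside their central 95%, where random lists had a median of -0.50. Ccnd1, a cyclin of the G1 phase, was lower in both types (-1.26 and -3.19), as the 1 of 23 members so called. Pcna, a replication clamp, differed by 0.16 and -1.11, Mcm7 by 0.50 and -0.23, and Aurkb by 0.96 and 0.11. The folds of 2664 genes differed by 1 log2 unit or more between the library types. The 5 with the largest difference were Snord55, Snord35a, Mir1905, Snord99 and Mir29c, each listed at 0 in at least 1 library. 25 genes were called in opposite directions, 17 higher in the standard and lower in the TELP N9 libraries and 8 the other way, and 15 of the 25 were small noncoding RNAs. TELP N9 folds minus standard folds had a median of -0.27 and an SD across genes of 1.30, or 0.89 without small noncoding RNAs.

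The fourth comparison set N9_ss against N9 at day 7. Adipocyte genes were alike in both columns, with Fabp4 at 25399.5 and 24892 RPKM and Adipoq at 1961 and 2018. Of 10334 genes 2 were higher in N9_ss, Prl2c4 (1.83) and Rpl34 (1.01), and 1 was lower, Prl2c3 (-1.92). Prl2c3 and Prl2c4 are close copies, and Rpl34-ps1, a pseudogene of Rpl34, was next lowest at -0.85, so these values are uncertain, since copies can share reads, which was not tested. Pet117 (0.81), Psma3 (0.70), Plac9a (0.67) and Pop4 (0.64) were next highest, and Gm10052, H2-Q2, Srrd and Rsc1a1 next lowest. Small noncoding RNAs had a median of -0.07 and histones of -0.06, the step between the read values of the columns. Oxidative phosphorylation had a median of 0.11 and extracellular matrix of 0.10.

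Reads of N9 recur in N9_ss. In units of reads, 86.0% of 3469 genes under 1 RPKM in N9 had equal values within 0.1%, while between the standard libraries of day 0 and day 7 10.5% of low genes share one ratio. Over 1402 low genes with whole reads recovered, 92.5% had equal reads, against 17.2% expected of independent libraries. Among all 13820 genes 5386 had equal reads, 7966 had more in N9_ss and 468 fewer. The columns differed by less than separate libraries would, and were not used as replicates of each other.

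**Figure D4:**
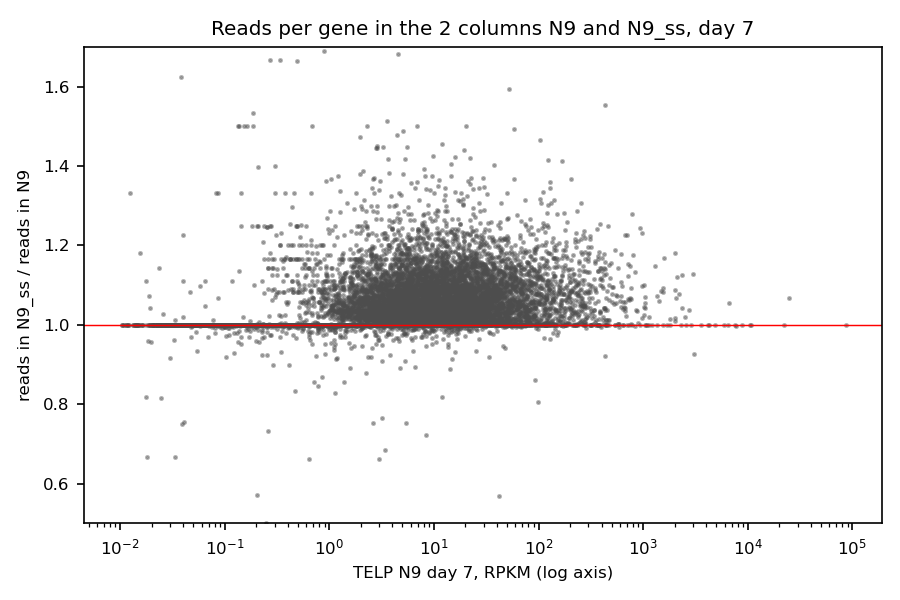
Reads in N9_ss divided by reads in N9 for 13750 genes at day 7, against RPKM in N9 on a log axis. The red line marks equal reads, and 29 genes lie beyond the ratio axis. Points at low RPKM lie mostly on the line, and 7966 of 13820 genes have more reads in N9_ss.

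The fifth comparison set T18 against N9 at day 7. Fat cell genes were lower in T18, as were most genes, with Fabp4 at 3957 against 24892 RPKM, Adipoq at 491 against 2018 and Cidec at 96.1 against 2357. Adipoq, at -2.04 log2 units, lay near the median of -2.07 of random lists matched to the adipocyte list. Plin4 differed by -5.45, Pck1 by -5.54 and Lipe by -5.17 log2 units. Fatty acid oxidation had a median of -3.39 with 22 of 22 lower, led by Acaa1b (-5.75), Acads (-5.14) and Hadha (-3.97). Oxidative phosphorylation had -2.34 with 38 of 40 lower, at percentile 6.05, inside the central 95% of random lists. The TCA cycle had -3.14 with 16 of 16 lower, including Mdh2 (-4.12), Cs (-3.86) and Idh3a (-3.85). Thermogenic genes had -3.72, with Elovl3 at -5.25 and Cpt1b at -4.96, and the medians of fatty acid oxidation, TCA cycle and thermogenic genes lay at or below percentile 0.03. Adipocyte identity had -2.65 (percentile 0.66) and lipogenesis -2.57 (percentile 2.41), where Slc25a1 was at -3.78.

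Proliferation had a median of -0.94 (percentile 99.98) with Aurkb at -2.18, Mcm7 at -1.73 and Pcna at -1.53 among its 9 of 22 lower. Cytosolic ribosomal protein genes had -1.25, with Rpl30 at -6.38, Rpl7l1 at -2.52 and Rpl13a at -2.21. Histones had -0.42, preadipocyte genes -1.25 with Twist2 at -2.68 and Pdgfrb at -1.80, and the matrix list -1.56 with Thbs1 at -4.77 and Col6a2 at -3.93. Interferon and inflammation genes had -0.31, BMP and TGF-beta targets -0.96, and glucocorticoid targets -1.17, with Dusp1 at -4.13. The medians of these lists and of the ribosomal protein, histone, preadipocyte and matrix lists lay at percentile 98.3 or above, so these lists fell less than random lists did. Stress genes had -2.50 at percentile 0.84, with 11 of 11 lower and Atf4 at -3.60, and osteoblast markers had 0.00 over 3 members. Snord111, Snord42b, Snord49b, Mir5046, Snora20 and Snord87 were highest in T18 and were all listed at 0 in N9. Mir6986, Snord65, Mir8114, Snord69, Snord47 and Snord100 were lowest, and were all listed at 0 in T18.

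Of 9753 genes 8130 were lower and 82 higher in T18, and the median of all genes was -1.77. Under median of ratios the median was -0.12, with 1344 lower and 932 higher, and under quantile normalization 1211 and 970. Only order among lists can be read from this comparison, since medians of preadipocyte, matrix, proliferation, histone and ribosomal protein genes turn positive under both scalings. Small noncoding RNAs held 80.5% of the RPKM of T18, against 35.7% in N9 and 9.18% in standard day 7. RPKM divides by length, so these are not shares of reads. Chosen after their values were seen, Mir6236 was at 221011 RPKM, Rnu12, a spliceosomal RNA, at 144629, Rmrp, the RNA of a ribonuclease, at 37616 and Lars2 at 26494. Levels of N9 and T18 had r = 0.777 across genes, and those of standard day 7 and T18 r = 0.724.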

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

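Most tests below were chosen after the results were seen, namely those of library type, scaling, extent of differentiation between the N9 and standard libraries, short effective length, feature length, a day 7 change in small noncoding RNAs, read number and dilution. The tests of small noncoding RNA change and of dilution took the place of others set beforehand, after the results of those had been seen, and the 2 lists in the dilution test were picked with their medians known. The test of less complete differentiation behind T18 was set before its result was seen.

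The day 7 fold of proliferation genes lay on opposite sides of 0 in the library types, at 0.36 in the standard (percentile 100) and -0.92 in the TELP N9 libraries (percentile 5.05, inside the central 95% of random lists). With 1 library per group, the difference was not tested. In addition, 25 genes were called in opposite directions by the library types, 15 of them small noncoding RNAs, and this too was not tested.

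Metabolic genes were higher and matrix genes lower in TELP N9 than in the standard library at day 7. A preference of the library type would act at day 0 too, but the metabolic difference was larger at day 7 by a median of 0.84 (0.77 to 1.01), with day medians of -0.01 and 0.90. Matrix genes were not in that test. Their median was already -0.26 (-0.38 to -0.14, percentile 0) at day 0, against -2.09 at day 7, so some effect of library type on them stays open. One scaling factor would move both groups alike, yet metabolic and matrix medians lay 2.99 apart (2.17 to 3.35). Across genes, with small noncoding RNAs left out, the day 7 difference followed the standard day 7 fold with r = 0.46 (0.44 to 0.48). The standard day 7 library enters both with opposite signs and alone would push r below 0. A candidate explanation is therefore a further differentiated culture behind the TELP N9 library. Proliferation genes did not follow that pattern, with a median of 0.36 in the standard fold and -1.35 in the day 7 difference. Nor did stress and early response genes, at -0.25 (percentile 31.3, inside the central 95% of random lists) and 1.04. The labels do not say whether both libraries came from 1 RNA, and a type effect that acts only in adipocyte RNA stays open.

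Small noncoding RNAs took extreme and conflicting values. Of 42 called in both library types 27 had the same direction (64.3%, exact binomial interval 48.0% to 78.4%), so a change with differentiation stays open. Of 221 called in either type 12.2% were called alike in both, but 138 lay under 0.01 RPKM in both libraries of a type and could not be called there, so that share decides nothing. Division by a very short effective length may inflate single reads, but the share of nonzero values at 1 RPKM or more in N9 day 7 was 82.4%, against 73.9% in other genes, short of the 90% set for it. That share also counts residual values such as Mir1892 at 0.00133 RPKM, so the missed bound does not argue against a short effective length. A second test of that idea, added after the first had missed its bound, found rho = -0.53 (-0.64 to -0.41) between length and the lowest nonzero value over 276 RNAs, but RPKM divides by length, which largely fixes that sign, so these explanations cannot be told apart.

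T18 lay below N9 in most genes. The depth of T18 was 0.866 of that of N9, but RPKM already divides by the read total, so this ratio cannot decide whether fewer reads on messenger RNAs played a part. One dilution of all messenger RNAs alike would leave lists near random lists of like expression. Of 19 lists with a median, 16 lay outside the central 95% of these, small noncoding RNAs among them. Fatty acid oxidation (-3.39, percentile 0) fell more and proliferation (-0.94, percentile 99.98) less. These values argue against one dilution as the whole cause for this pair of libraries, while a partial dilution stays open. At 10 RPKM or more in N9, fatty acid oxidation genes lay -2.12 (-2.41 to -1.76) from ribosomal protein genes. These lists were picked with their medians known, so their gap decides nothing alone. The test set beforehand, of adipocyte and metabolic against matrix and contractile genes, gave -0.76 (-1.53 to -0.18), too wide to decide alone. Less complete differentiation may contribute, since T18 minus N9 was lower where the standard day 7 fold was higher. This held across 4691 genes at 10 RPKM or more in N9 (r = -0.31, -0.35 to -0.28). Within bins of N9 level r was -0.29, a check added afterwards. The N9 day 7 library enters this test and also that of N9 against standard, so a trait of that library alone could give both results. No T18 library of day 0 was analysed here, so an effect of the T18 procedure on these genes stays open.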

How the results depend on the processing

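The limma fit, the scalings, pseudocounts, filters and library swaps were planned, and the counts without small noncoding RNAs or genes listed at 0 were chosen after seeing the data. Of the values that answer a comparison, 85 stayed within their bounds and 31 moved, not counting 5 with N9_ss in place of N9, which share its reads and could hardly move. Of the others 362 stayed, 93 moved and 19 changed sign, counting a sign only where the median lay outside the central 95% of random lists. Another 11 medians inside it changed sign and are among those that stayed or moved. The cause was not tested except where a setting's construction gives it. Depth limits low genes most in T18, where 1 RPKM of a 2 kb transcript is 8.56 reads. No paired analysis was possible because RNA groups share fewer than 2 replicate numbers, and the chromatin groups were not analysed here. The limma block pairs the days within each library type, not by replicate number.

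Genes called at day 7 in both types were 162 higher and 24 lower past limma with library type as block, whose 1 residual degree of freedom limits it, and 199 were higher with T18 in place of N9. With T18 in that place TELP gave 284 higher and 9539 lower, and under quantile normalization TELP N9 gave 2223 lower. Genes higher in TELP N9 than standard at both days were 117 with a pseudocount of 0.1 RPKM and 21 under equal totals. Genes lower at both days were 45 under equal totals, 5 without small noncoding RNAs and 8 without genes listed at 0. N9_ss against N9 gave 1 higher and 0 lower at a mean of at least 5 RPKM, and 1 higher under quantile normalization. T18 against N9 gave 4865 lower at that filter, which tests fewer genes, 932 higher and 1344 lower under median of ratios, 970 and 1211 under quantile normalization, and 48 higher without small noncoding RNAs.

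The correlation of day 7 folds was 0.589 with a pseudocount of 0.1 RPKM and 0.504 with T18 in place of N9. Level correlations with that pseudocount, no filter and a filter at 5 RPKM were 0.814, 0.966 and 0.805 for standard and TELP N9 at day 0. They were 0.725, 0.923 and 0.665 at day 7, and 0.729, 0.874 and 0.672 for N9 and T18.

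Medians of T18 minus N9 that changed sign were, under median of ratios and quantile normalization in turn, 0.30 and 0.34 for preadipocyte genes, 0.39 and 0.41 for extracellular matrix, 0.50 and 0.54 for proliferation, 0.40 and 0.44 for BMP and TGF-beta targets, 0.74 and 0.87 for glucocorticoid targets, 0.85 and 0.87 for interferon and inflammation, 1.44 and 1.51 for osteoblast markers, 1.32 and 1.38 for histones, and 0.88 and 0.78 for ribosomal proteins. Small noncoding RNAs had 0.66 under median of ratios.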

Other observations

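Genes were grouped into families by the stem of their symbols after the fixed lists had been examined. Some families, such as Cox, Ndufa and Ndufb, share members with those lists. Of 116 families with at least 10 measured members, 21 lay outside the central 95% of random lists on one side in both library types, 14 above and 7 below. Lying above random lists is not being higher at day 7, and Tmem genes had medians of 0.03 and -0.02. Peroxisome biogenesis genes (Pex) had medians of 0.83 and 1.77 in the standard and TELP N9 libraries, with Pex16 at 3.22 and 4.70. Mitochondrial ribosomal proteins of the large subunit (Mrpl) had 0.58 and 0.97 over 48 members, 7 of them called higher in both, with Mrpl12 at 2.17 and 3.38. Cytosolic ribosomal protein genes had medians of -0.75 and -1.36, though 1 of 82 was called lower in both. Inner membrane translocase genes (Timm) had 1.03 and 1.47, with 8 of 13 higher in both, such as Timm10 at 1.26 and 2.10. Mitochondrial carriers (Slc25a) had 0.43 and 1.04 over 37 members, with 10 higher and 1 lower in both and Slc25a10 at 3.92 and 4.66, and aldehyde dehydrogenases (Aldh) had 0.79 and 1.05, with Aldh1a7 at 7.06 and 7.21.

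Families with medians below those of random lists included the Adamts proteases, which cleave matrix proteins, with medians of -1.03 and -1.88 and 7 of 13 lower and 1 higher in both. Adamts1 differed by -2.03 and -4.05 and Adamts5 by -1.94 and -4.60. Semaphorins (Sema) had -0.77 and -1.41, with 4 lower and 1 higher of 10 members in both and Sema3a at -2.51 and -2.81. Zinc finger genes (Zfp) had -0.40 and -0.94 over 289 members, with 9 lower and 0 higher in both, a smaller share than the 667 lower of all 11474 genes. Intraflagellar transport genes (Ift), which build cilia, had -0.76 and -1.34, though only 1 of 14 was called lower in both. Medians of the families named here other than Tmem kept their direction under median of ratios, equal totals and quantile scaling. The families and the genes named for them were chosen after their values were seen.

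Lox, which encodes a collagen crosslinking enzyme and was singled out after its values were seen, was at 750 RPKM in standard day 0 and listed at 0 in TELP N9 day 0. It stood at 426 RPKM in standard day 7 and 42.9 in N9 day 7.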
